A study of Mus musculus with 6 samples.

How the data were processed

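Messenger RNA was profiled by sequencing in 6 libraries of NIH3T3 cells, an immortalised mouse embryonic fibroblast line. Per the labels, 3 libraries came from cells given the solvent DMSO and 3 from cells given IPRN, and groups and replicate numbers were taken from those labels. Per the labels' protocols, polyadenylated RNA was captured on oligo(dT) beads, fragmented, reverse transcribed with random primers and amplified by PCR after adapter ligation. No step in that protocol marks the strand, so reads from overlapping genes on opposite strands cannot be separated.

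The authors deposited 1 table per library, and per the file headers each holds a count and an FPKM value per Ensembl gene. The deposited counts were whole numbers, without normalization, for 55401 genes, of which 28233 had a count of 0 in every library. The deposited FPKM values, which the authors scaled by gene length and library size, served only to check the counts and were not tested. In that check over 9401 genes, the gene length implied by each count and FPKM pair had a median SD of 0.00219 on the log2 scale across libraries. The lowest FPKM listed was 0.0001, which held 61.8% of the values. Per the submitters' processing notes, cutadapt 1.9 was used. The aligner, the counting tool, its handling of strand and of multiply mapped reads, the genome build and the annotation are not given in the sources used here. Of 55141 gene IDs shared with GENCODE release M21, 51957 (94.2%) had the identical chromosome, start, end and strand on GRCm38, so positions are given on that build. Among the genes tested, 6184 shared part of an exon with another gene model on either strand, and the report says which of the genes it names are among them, since their values are uncertain.

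Total counts per library ran from 60320282 to 78629444. A floor of 3 counts corresponded to between 0.0382 and 0.0497 CPM (counts scaled to the library total). The floor covers counting error only, since PCR copies were not told apart. The 95% intervals given below were taken over genes, not libraries. Counts of replicate pairs differed by far more than sampling noise (chi-square per degree of freedom from 34.0 to 97.6), so each library was counted as a separate sample. The pairs that held IPRN 1 stood highest, at 89.9 and 97.6, against 34.0 to 48.8 for the other pairs. The labels do not say whether replicates were separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

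Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, its default expression filter on the groups (a minimum count of 10), and the quasi-likelihood test with group as the only term. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 17159 genes that passed the filter, and a gene was called changed at an adjusted p under 0.05. Standard errors were derived from the log2 fold change and the F statistic. Gene values are TMM-normalised CPM with the SD over 3 libraries. All adjusted p-values of single genes come from this edgeR test unless another tool is named.

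Before the data were examined, 24 response lists and 7 lists of other cell types and mitochondrial transcripts were fixed from textbook knowledge. Of their 672 symbols, 652 were listed in the tables. Response lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided and adjusted over the 24 lists, and again with an estimated correlation and with fry. Aldoa, a glycolytic enzyme, has 2 gene models, so the hypoxia and glycolysis list holds 29 tested genes from 28 symbols. Shares of the total count and summed marker values were compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. Genes were named by a rule fixed beforehand. It took the 10 largest rises and 10 largest falls among changed genes with a mean of at least 5 CPM, non-overlapping groups and a standard symbol. It added the 3 members with the smallest adjusted p of each response list that was called or held at least 3 changed members, 8 fibroblast activation markers and 2 aryl hydrocarbon receptor targets. Members of a list that are only counted were named without values, and those names were chosen after their values were seen. Some genes that meet the rule or are counted in a list are not reported here by name.

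On simulated counts for IPRN against DMSO over 16491 genes, the edgeR test recovered 25.4% of genes changed by 1.5-fold, 68.7% at 2-fold and 83.3% at 4-fold, with 4.84% false calls. DESeq2 1.42.0 recovered 47.8%, 86.6% and 93.9%, with 26.2% false calls. The counts were drawn once from dispersions estimated by edgeR, and only 67, 67 and 66 genes were changed at these folds. With 1 of 24 simulated lists raised 1.5-fold over 17159 genes, camera called that list and 0 of the 23 others. Genes were simulated independently of one another, so this does not show how camera behaves on lists of correlated genes.

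Alternatives fixed beforehand were median-of-ratios and upper-quartile scaling, no filter, a mean of at least 50 counts, the replicate number as a block, each library left out in turn, DESeq2, an estimated correlation and fry. Alternatives on the pseudocount applied to normalized values only and were not run. Alternatives added after the data were seen were a term for the 4 libraries with liver transcripts, leaving out both libraries that lack them, a test on protein-coding genes with no exon overlap, and robust dispersion. Marker lists for 8 tissues or cell types, and pathways as annotated in the deposited tables, were also added at that stage, as was the count of calls over all changed list members with 1 library left out.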

Results

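The transcriptome of NIH3T3 mouse fibroblasts was measured by mRNA sequencing after treatment with IPRN or with DMSO, the vehicle. The series title names angelicin, a plant furanocoumarin, and its design text describes hydrogen peroxide and TGF-β as stimuli meant to place the cells in a state like that of cancer-associated fibroblasts. The sample labels give the treatment only. They state no dose or time, and they do not say whether the DMSO cells received both stimuli as well. Each group held 3 libraries. Total counts were 60320282, 72687081 and 78629444 in DMSO 1, 2 and 3, and 72444710, 74183334 and 63594179 in IPRN 1, 2 and 3. Between 20228 and 21941 genes had at least 1 count per library.

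The comparison of IPRN with DMSO asked which signalling pathways the compound altered in these fibroblasts. Of the lists of immediate early, inflammatory fibroblast and cholesterol synthesis genes, 21 of 30, 13 of 27 and 13 of 23 tested members fell under IPRN, and camera called all 3 lists down (adjusted p = 0.00320 with an estimated correlation for each). Nr4a1, an orphan nuclear receptor induced within minutes of stimulation, fell from 333.8 ± 11.4 to 69.1 ± 3.59 CPM (SD, n = 3), and Lif, a cytokine of the interleukin-6 family, from 218.2 ± 4.54 to 47.5 ± 2.29 CPM. Tlr4, the receptor for bacterial lipopolysaccharide, rose 5.44-fold, from 4.61 ± 0.202 to 25.1 ± 0.519 CPM. Most other changes were smaller than 2-fold.

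In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 938 of 17159 genes changed (5.47%), of which 422 rose and 516 fell. Of these, 88 changed at least 2-fold, with 13 rises and 75 falls. The values of the groups did not overlap for 29.6% of all tested genes, against 10% by chance. With 1 library left out, the count was 133 without DMSO 1, 144 without DMSO 2, 185 without DMSO 3, 235 without IPRN 2 and 262 without IPRN 3, but 1047 without IPRN 1. The count at 2-fold or more was 52 without DMSO 1, 56 without DMSO 2 and 53 without DMSO 3. Of 136 changed members of the 24 gene lists described below, 53 stayed called in all 6 fits with 1 library left out, 15 were not called in 1 to 3 of these fits, 62 were not called in 4 or 5, and 6 (Ccnb1, Csf3, Il11, Mcoln1, Pmvk and Stat2) were called in none. DMSO 1 and IPRN 3 stood apart in carrying almost no liver transcripts (22 genes summed to 0.348 and 1.09 CPM, against 36.7 to 127 CPM in the other 4 libraries). Without both of them 53 genes were called, 43 of them at least 2-fold, and a term for the libraries with liver transcripts gave 429.

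Tlr4 (ENSMUSG00000039005, a protein-coding gene on chromosome 4 from 66827584 to 66930284, plus strand, GRCm38) had a log2 fold change of 2.44 ± 0.086 (SE) and an adjusted p of 5.30e-05 in edgeR. Csnk1g1, a casein kinase 1 isoform (ENSMUSG00000032384, chromosome 9 from 65908924 to 66045015, plus strand), rose 2.74-fold from 15.1 ± 0.913 to 41.4 ± 3.06 CPM. Ier5l, a relative of the immediate early gene Ier5, rose 1.94-fold to 82.4 ± 2.45 CPM. Also among the 10 largest rises were Pex26, needed for peroxisomal protein import (2.34-fold), the growth arrest gene Gadd45g (2.23-fold), Men1, which encodes the tumour suppressor menin (2.06-fold), the zinc finger gene Zfp658 (2.02-fold), the transcriptional repressor gene Snai1 (1.92-fold) and the kinase gene Nuak2 (1.88-fold). Pex26 shared an exon stretch with another gene model, so its value is uncertain. Tlr4, Csnk1g1 and Ier5l stayed called whichever library was left out. Without DMSO 1 the adjusted p was 0.0525 for Gadd45g and 0.0598 for Nuak2. Leaving out any DMSO library ended the calls of Men1 (adjusted p from 0.0584 to 0.0714) and Snai1 (0.0852 to 0.115), and also that of Zfp658 (0.0577 to 0.0974, including the fits without IPRN 2 or IPRN 3). IPRN 1, 2 and 3 held 91.2, 65.3 and 67.4 CPM of Men1 and 186.3, 125.7 and 125.4 CPM of Snai1. Without IPRN 1 both stayed called, but their log2 fold changes were smaller, at 0.87 against 1.04 for Men1 and 0.73 against 0.94 for Snai1. Pex26 was not called without DMSO 1, DMSO 2, IPRN 1, IPRN 2 or IPRN 3 (0.0594 to 0.121).

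**Figure D1:**
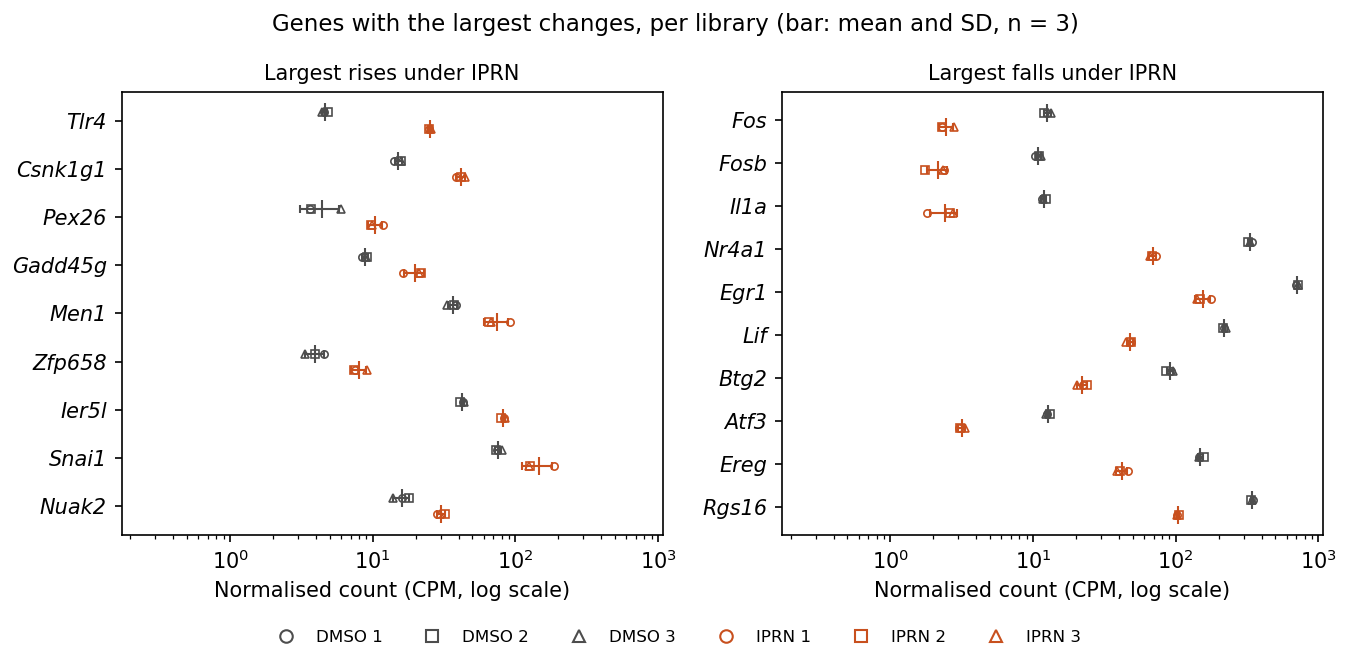
Normalised counts (CPM, log axis) of genes named in the text from the 10 largest rises (left) and of the 10 largest falls (right) in each library, with DMSO in grey and IPRN in rust, symbols for replicates, and bars for the mean and SD (n = 3). Tlr4 lay between 4.42 and 4.82 CPM in the DMSO libraries and between 24.6 and 25.6 CPM in the IPRN libraries, and the groups did not overlap for any gene shown.

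Immediate early and MAPK feedback genes, the transcription factors and phosphatases that follow growth factor signalling, fell as a group. Of 30 tested members, 21 fell, 0 rose and 9 did not pass, with a median log2 fold change of -0.79 (camera adjusted p = 2.86e-81, and 0.00320 with an estimated correlation). When adjusted over the list alone, 24 fell and 2 rose. The AP-1 subunit genes Fos and Fosb were 5.11-fold and 5.04-fold lower, at 2.47 ± 0.279 and 2.16 ± 0.352 CPM under IPRN. Nr4a1 (ENSMUSG00000023034, chromosome 15 from 101254269 to 101274795, plus strand) fell by 2.27 ± 0.057 (SE) on the log2 scale with an edgeR adjusted p of 1.07e-05. Egr1, a zinc finger transcription factor gene (ENSMUSG00000038418, chromosome 18 from 34859823 to 34864984, plus strand), was 4.60-fold lower, from 713.8 ± 10.7 to 155.3 ± 18.0 CPM. Ier2 was 2.33-fold lower at an adjusted p of 7.13e-05. Outside this list, other large falls were those of Rgs16, which encodes a GTPase activator for G proteins (3.33-fold), and of Ereg, a ligand of the EGF receptor (3.55-fold). Both overlap another gene model on an exon, so their values are uncertain. The 10 largest falls all stayed called whichever library was left out.

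Inflammatory fibroblast genes were also called down: 13 of 27 tested members fell, 1 rose and 13 did not pass, with a median of -0.51 (camera adjusted p = 1.65e-36, and 0.00320 with an estimated correlation). The counts adjusted over the list alone were 16 falls and 1 rise. Lif (ENSMUSG00000034394, chromosome 11 from 4257557 to 4272514, plus strand) was 4.59-fold lower at an edgeR adjusted p of 1.07e-05. Ptgs2, the inducible cyclooxygenase, was 3.14-fold lower, from 1073 ± 51.6 to 342.1 ± 10.6 CPM, and the neutrophil chemokine gene Cxcl5 3.16-fold lower, from 541.2 ± 27.4 to 171.5 ± 6.78 CPM. Il1a, which is not in this list, encodes interleukin-1α and shares an exon stretch with another gene model. It was 4.93-fold lower, at 2.40 ± 0.516 CPM under IPRN. The list member that rose was Csf1, the macrophage colony-stimulating factor gene.

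**Figure D2:**
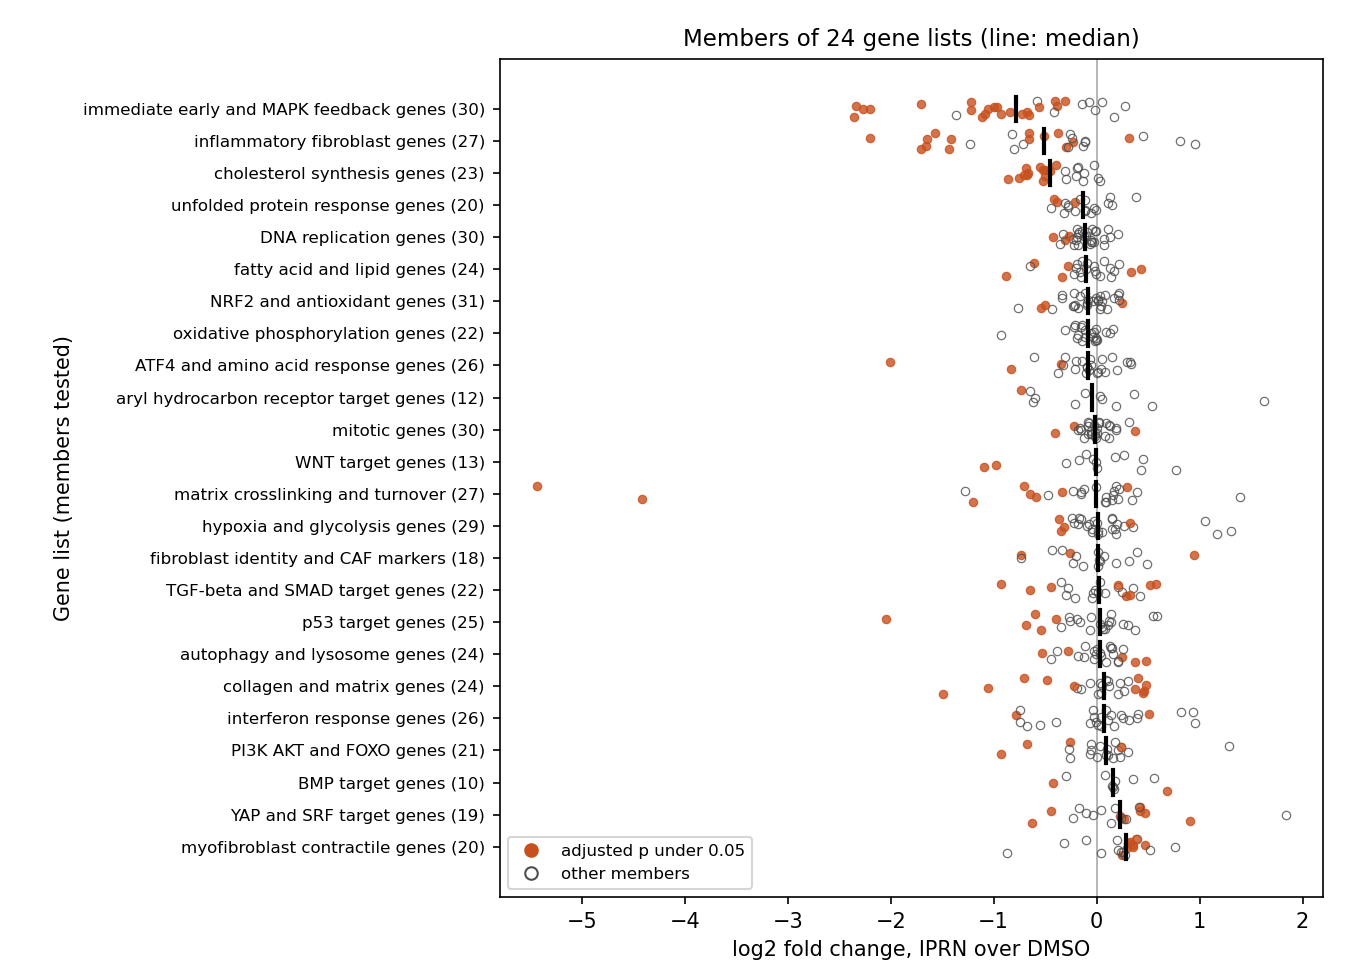
Log2 fold change (IPRN over DMSO) of every tested member of the 24 gene lists, ordered by list median (black line), with members at an adjusted p under 0.05 filled. The lowest medians belonged to the immediate early (-0.79), inflammatory (-0.51) and cholesterol synthesis lists (-0.46), and the highest to the myofibroblast contractile list (0.29). The 2 points furthest to the left are Mmp10 and Mmp13, which had few counts.

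Cholesterol synthesis genes were called down, with 13 of 23 tested members lower, 0 higher and 10 that did not pass (median -0.46, camera adjusted p = 4.52e-22, and 0.00320 with an estimated correlation). The count of falls adjusted over the list alone was 17. Insig1, a sterol-regulated protein that holds back SREBP activation, was 1.81-fold lower, from 173.6 ± 5.36 to 95.8 ± 1.68 CPM (edgeR adjusted p = 0.000250). Cyp51, the lanosterol demethylase gene, was 1.60-fold lower and Hmgcs1, the HMG-CoA synthase gene, 1.41-fold lower. Cyp51 and Hmgcs1 overlap other gene models on an exon, so the sizes of their changes are uncertain.

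Of 20 tested myofibroblast contractile genes 8 rose, 0 fell and 12 did not pass, with a median of 0.29 (camera adjusted p = 1.94e-07). The call of this list was lost with an estimated correlation (adjusted p = 0.176 with an estimated correlation), and adjusted over the list alone 14 rose. Flna, the actin crosslinker filamin A, rose 1.31-fold from 2295 ± 22.97 to 2997 ± 56.3 CPM (edgeR adjusted p = 0.00388). Flna was not called without DMSO 1 and IPRN 3 together (0.153) or with replicate number as a block (0.0536). Cnn2, or calponin 2, rose 1.38-fold and Itga5, the α5 subunit of the fibronectin receptor, 1.28-fold. Acta2, or α-smooth muscle actin, the usual marker of myofibroblasts, rose 1.18-fold from 2328 ± 41.6 to 2755 ± 68.4 CPM at an adjusted p of 0.0233. Cnn2 was not called without DMSO 1 (adjusted p = 0.0514) and Itga5 was not called without DMSO 1 or DMSO 2 (0.0691 and 0.0714). Acta2 was called without IPRN 1 but not without DMSO 1, DMSO 2, DMSO 3, IPRN 2 or IPRN 3 (0.0645 to 0.117).

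Targets of YAP and SRF, which respond to actin and cell tension, split in direction: 6 of 19 tested members rose, 2 fell and 11 did not pass, with a median of 0.23 (camera adjusted p = 0.0274, direction up). That call was lost with an estimated correlation (adjusted p = 0.217 with an estimated correlation) and without IPRN 1 (0.0998). Adjusted over the list alone, 7 rose and 3 fell. The members that rose were Actb, Ajuba, Amotl2, Axl, Crim1 and Nuak2. Both that fell encode secreted matricellular proteins: Ccn1 was 1.54-fold lower, from 856.7 ± 14.3 to 554.8 ± 45.3 CPM, and Ccn2, which overlaps another gene model, 1.36-fold lower. Their adjusted p-values in edgeR were 0.00508 and 0.00631.

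Collagen and matrix genes were divided, with 5 of 24 tested members higher, 5 lower and 14 that did not pass. The median was 0.068, the mean -0.03, and camera called no direction (adjusted p = 0.888, up). Restricted to protein-coding genes without exon overlap, an alternative added after the data were seen, camera called the list down (adjusted p = 0.0413, against 0.396 to 0.987 in the fits without 1 library). All 5 members that rose overlap other gene models and were dropped by that restriction, while Lum and Postn, which fell, were kept. That call therefore cannot be told apart from the loss of those members. Adjusted over the list alone, 9 rose and 6 fell. The collagen genes Col4a1, Col4a2 and Col5a1 rose, as did Fbn1 and Fn1, which encode fibrillin 1 and fibronectin. The small proteoglycan genes Dcn and Lum fell, together with Postn, Thbs1 and Thbs2, which encode matricellular proteins. Lum was 2.82-fold lower, from 14.8 ± 0.214 to 5.23 ± 0.420 CPM, Postn 1.63-fold lower and Thbs1 1.40-fold lower, with edgeR adjusted p-values of 0.000716, 0.00336 and 0.00163. Col5a1 rose 1.37-fold and Fn1 1.29-fold, to 6474 ± 398.2 CPM. Col5a1, Thbs1 and Fn1 overlap other gene models on an exon. Fn1 was not called without DMSO 1, DMSO 2, DMSO 3 or IPRN 2 (adjusted p from 0.0509 to 0.0854). Col1a1, the main fibrillar collagen gene, measured 6081 ± 196.8 CPM in DMSO and 7004 ± 982.1 CPM in IPRN, which did not pass (adjusted p = 0.292) except without IPRN 1 (0.00854).

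Genes of matrix crosslinking and turnover were called down by camera (adjusted p = 0.00694) although their median was -0.0047. Of 27 tested members 7 fell, 1 rose and 19 did not pass. The call was lost with an estimated correlation (adjusted p = 0.108 with an estimated correlation), without IPRN 1 (0.112) and with a filter on genes averaging 50 counts (0.163). Adjusted over the list alone, 9 fell and 5 rose. The members that fell were the secreted proteases Adamts1, Adamts5, Mmp10, Mmp13, Mmp19 and Plau with the Plau receptor gene Plaur, and the member that rose was Mmp14, a membrane-bound collagenase. Adamts1 was 2.30-fold lower, from 69.8 ± 2.48 to 30.4 ± 1.04 CPM (edgeR adjusted p = 0.000188), and Adamts5 fell from 77.4 ± 3.58 to 51.4 ± 1.41 CPM. Mmp19, which overlaps other gene models, was 1.57-fold lower.

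TGF-β and SMAD targets had no common direction. Of 22 tested members 5 rose, 3 fell and 14 did not pass (median 0.024, mean -7.76e-05, camera adjusted p = 0.888), and adjusted over the list alone 7 rose and 5 fell. Bhlhe40, Ltbp2, Ltbp3, Pmepa1 and Smurf1 rose, and Ccn2, Il11 and Junb fell. Pmepa1, a feedback inhibitor of TGF-β signalling, rose 1.49-fold from 115.7 ± 2.43 to 171.9 ± 5.93 CPM (edgeR adjusted p = 0.00200), and the AP-1 gene Junb, which overlaps Prdx2, was 1.91-fold lower. Tgfb1 itself measured 47.6 ± 2.43 and 56.7 ± 9.90 CPM, which did not pass (adjusted p = 0.298). BMP targets were called up by camera (median 0.16, adjusted p = 0.0395) with 1 of 10 tested members higher, 1 lower and 8 that did not pass. That call was lost with an estimated correlation (adjusted p = 0.234 with an estimated correlation) and without DMSO 2, DMSO 3, IPRN 1 or IPRN 3 (0.0581 to 0.149). There were 4 rises and 2 falls adjusted over the list alone. Id1, an inhibitor of helix-loop-helix transcription factors, rose 1.61-fold from 64.9 ± 1.07 to 104.2 ± 2.60 CPM (adjusted p = 0.000862). Grem1, which encodes a BMP antagonist, was 1.34-fold lower, but it was called only with all 6 libraries or without IPRN 1 (adjusted p from 0.0581 to 0.149 with DMSO 1, DMSO 2, DMSO 3, IPRN 2 or IPRN 3 left out).

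Fibroblast identity and cancer-associated fibroblast markers showed 1 rise and 2 falls among 18 tested members, with 15 that did not pass (median 0.015, mean -0.03, camera adjusted p = 0.418, down). There were 3 rises and 7 falls adjusted over the list alone. Pdgfra, the α receptor for platelet-derived growth factor, was 1.67-fold lower, from 188.6 ± 2.09 to 113.3 ± 2.28 CPM (edgeR adjusted p = 0.000351), with overlapping gene models on its exons. Prrx1, a mesenchymal homeobox gene, was 1.20-fold lower and was not called with DMSO 1, DMSO 2, DMSO 3, IPRN 2 or IPRN 3 left out (0.108 to 0.149), and the rise was that of Snai1. Among markers fixed beforehand, the intermediate filament gene Vim measured 1468 ± 36.4 and 1343 ± 18.8 CPM (adjusted p = 0.119), and the receptor gene Pdgfrb 137.6 ± 2.40 and 141 ± 6.41 CPM (adjusted p = 0.761). Neither passed. Fap, the fibroblast activation protein gene, had 0 counts in 5 libraries and 4 counts in IPRN 3, so a difference was not detectable at this depth.

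Camera called 4 lists of stress and growth genes down, each with 5 or fewer members that fell. In the p53 list 5 of 25 tested members fell and 0 rose, with a median of 0.033 and a mean of -0.11 (camera adjusted p = 0.00460; adjusted p = 0.108 with an estimated correlation, and 0.0522 without IPRN 1). Those that fell were Btg2, Eda2r, Mdm2, Plk2 and Plk3, and among these Btg2, an antiproliferative gene that also responds early to growth factors, was 4.12-fold lower and the kinase gene Plk2 1.60-fold lower. Eda2r was not called with DMSO 1, DMSO 2, DMSO 3 or IPRN 2 left out (0.0505 to 0.0602). In the unfolded protein response list 3 of 20 fell and 0 rose, with a median of -0.14 (0.00753; adjusted p = 0.108 with an estimated correlation, and 0.183 on protein-coding genes without exon overlap). Canx, Dnajc3 and Hsp90b1 fell, and Hsp90b1, a chaperone of the endoplasmic reticulum that overlaps other models, was 1.31-fold lower, but not called without DMSO 1 or DMSO 2 (0.0580 and 0.0588). Canx was not called in 5 of the 6 fits with 1 library left out (0.0747 to 0.168) and Dnajc3 in 4 (0.0623 to 0.0912). Among DNA replication genes 3 of 30 fell and 0 rose, with a median of -0.11 (camera adjusted p = 0.00829). That call was lost with an estimated correlation (adjusted p = 0.108 with an estimated correlation) and without DMSO 1 and IPRN 3 together (0.0679). Mcm6, Pola1 and Rrm1 fell, and Rrm1, a subunit of ribonucleotide reductase, was 1.24-fold lower but not called with DMSO 1, DMSO 2, DMSO 3 or IPRN 2 left out (0.0520 to 0.0718). Mcm6 (0.0835 to 0.135) and Pola1 (0.0525 to 0.123) each lost their call in 5 of the 6 fits. In the ATF4 list 3 of 26 fell and 0 rose, with a median of -0.082 (0.0146; adjusted p = 0.108 with an estimated correlation, and 0.112 without IPRN 1). Atf3, Ddit4 and Ppp1r15a fell. Among them Atf3, a stress-induced transcription factor gene, was 4.02-fold lower, and Ppp1r15a, a phosphatase subunit that overlaps Tulp2, 1.78-fold lower, though not called without DMSO 1 (0.0518). Ddit4 was called only with all 6 libraries or without IPRN 1 (0.0743 to 0.149 in the other fits). Adjusted over the list alone, 6 fell and 2 rose in the p53 list, 8 fell in the unfolded protein list, 9 fell in the replication list, and 9 fell and 4 rose in the ATF4 list.

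The remaining lists were not called by camera. Fatty acid and lipid genes had 2 rises and 4 falls among 24 (median -0.10, adjusted p = 0.123; 4 and 7 adjusted over the list alone), the rises being Angptl4 and Cpt1a. Acsl3, Acsl4, Elovl6 and Pdk4 fell, and Elovl6, a fatty acid elongase gene overlapping another model, was 1.52-fold lower. Angptl4 (0.0557 to 0.0885) and Acsl3 (0.0623 to 0.122) lost their call in 5 of the 6 fits with 1 library left out. Growth factor pathway genes of PI3K, AKT and FOXO had 1 rise and 3 falls among 21 (median 0.091, camera direction down, 0.888; 4 and 3 adjusted over the list alone), with Igf1r higher and Insr and Trib1 among those lower. The insulin receptor gene Insr fell from 48.6 ± 1.27 to 25.5 ± 1.60 CPM (edgeR adjusted p = 0.00144), and Trib1 was not called without DMSO 2, IPRN 2 or IPRN 3 (0.0514 to 0.0574). NRF2 and antioxidant genes had 1 rise and 2 falls among 31 (median -0.086, 0.143; 2 and 7 adjusted over the list alone), the rise being Pgd and the falls Gsta4 and Sod2. Pgd (0.0793 to 0.127) and Gsta4 (0.0801 to 0.129) lost their call in 5 of the 6 fits, and Sod2 did so when any DMSO library was left out (0.0747 to 0.0901). Among aryl hydrocarbon receptor targets 0 of 12 rose and 1 fell, Tiparp (median -0.041, 0.426; 2 and 1 adjusted over the list alone). Cyp1b1, a cytochrome P450 gene induced through that receptor, measured 47.9 ± 5.75 and 61.7 ± 2.84 CPM (adjusted p = 0.0781), and Cyp1a1 had 0 counts in 5 libraries and 8 in IPRN 3.

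Hypoxia and glycolysis genes, also not called, had 1 rise and 3 falls among 29 (median 0.011, mean 0.11, camera direction down, 0.888; 1 and 4 adjusted over the list alone), with Egln1 higher and Ddit4, Pgk1 and Vegfa lower. Egln1 (0.0514 to 0.132) and Vegfa (0.0573 to 0.0875) lost their call in 5 of the 6 fits with 1 library left out, as Ddit4 did. Interferon response genes had 1 rise, Stat2, and 1 fall, Ifit2, among 26 (median 0.071, 0.888; 2 and 2 adjusted over the list alone). Among WNT targets Dkk2 and Sfrp2 fell and 0 of 13 rose (median -0.0097, 0.467; 2 and 2 adjusted over the list alone). Autophagy and lysosome genes had 3 rises and 2 falls among 24 (median 0.036, 0.774; 4 and 3 adjusted over the list alone): Gabarapl1, Mcoln1 and Ulk1 rose, and Ctsl and Lamp2 fell. Among the fits with 1 library left out, Ulk1 and Lamp2 were called only without IPRN 1 (0.0629 to 0.133 and 0.0645 to 0.129 in the others), and leaving out any DMSO library ended the call of Ctsl (0.0542 to 0.0569). Mitotic genes had 1 rise, Plk1, and 2 falls, Ccnb1 and Top2a, among 30 (median -0.014, 0.956; 1 and 2 adjusted over the list alone). Ccnb1 lost its call in all 6 fits (0.0652 at the lowest), Top2a in 5 (0.0995 to 0.167) and Plk1 in 4 (0.0502 to 0.0773). Of 22 oxidative phosphorylation genes edgeR called 0 in either direction, over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05, and DESeq2 called 2, Cox7b and Uqcrc2. The list (median -0.084, camera adjusted p = 0.119) was not called, except down in the fit without IPRN 3 (0.0175). Among the genes named here and above without a value of their own, Acsl3, Bhlhe40, Col4a1, Col4a2, Crim1, Ctsl, Fbn1, Gabarapl1, Ltbp2, Ltbp3, Plk1, Plk3, Sfrp2, Tiparp, Top2a and Uqcrc2 overlap other gene models on an exon, so their calls are uncertain. Of the members named without values and not yet described in this respect, Acsl4, Ajuba, Amotl2, Axl, Bhlhe40, Col4a1, Cpt1a, Crim1, Csf1, Dkk2, Gabarapl1, Igf1r, Ltbp2, Mdm2, Mmp10, Mmp13, Mmp14, Pdk4, Pgk1, Plaur, Plk3, Smurf1 and Thbs2 were not called in 4 or 5 of the 6 fits with 1 library left out, and Actb, Ltbp3, Plau and Sfrp2 in 1 to 3.

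Signs of RNA quality were compared as shares of the total count. Mitochondrially encoded genes held 5.22 ± 0.0720% of counts in DMSO and 5.54 ± 0.920% in IPRN (exact permutation p = 1), with IPRN 1 highest at 6.60%. Ribosomal protein genes held 6.29 ± 0.0769% and 5.96 ± 0.315% (exact permutation p = 0.1, the smallest possible, and 0.5 after adjustment over 5 shares), with every IPRN library below every DMSO library and IPRN 1 lowest at 5.60%. The shares of histone genes, pseudogenes and ribosomal RNA had exact permutation p-values of 0.8, 0.7 and 0.8. In the 7 lists of other cell types and mitochondrial transcripts, edgeR called 0 of 48 tested members changed, with 6 at an unadjusted p under 0.05, and DESeq2 called 3, Cd14, Lpl and Csf1r, which overlaps another gene model. Summed macrophage and leukocyte markers stood at 145 CPM in IPRN 3, against 13.3 to 26.6 CPM in the other 5 libraries. Adipocyte markers summed to 58.9 ± 4.85 and 52.8 ± 2.78 CPM, neural and glial markers to 30.0 ± 3.32 and 31.7 ± 4.10 CPM, and endothelial markers to 4.64 ± 0.489 and 4.41 ± 1.09 CPM. Skeletal muscle markers summed to 3.26 ± 0.341 and 3.12 ± 1.08 CPM, and epithelial markers to 1.12 ± 0.632 and 2.29 ± 1.83 CPM. The exact permutation p of these sums lay between 0.2 and 1.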

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

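Of the settings below, the term for libraries with liver transcripts, leaving out both libraries that lack them, the restriction to protein-coding genes without exon overlap and robust dispersion were chosen after the data were seen. The number of changed genes, 938, stayed within 1.5 times under both other scalings, a filter at 50 counts, robust dispersion and the restriction, but that last count (939 of 8212 tested) shared only 605 genes with the main one. The count was 621 with no filter, 429 with the liver term, 2312 with DESeq2, 53 without both libraries and from 133 (without DMSO 1) to 1047 (without IPRN 1) with 1 library left out. Rises made up 45.0% of the calls, against 51.3% with DESeq2, 20.8% without both libraries and 21.8% to 43.4% with 1 library left out. The 88 genes changed at least 2-fold numbered 136 with DESeq2, 43 without both libraries and 52 to 94 with 1 library left out. Fits with libraries left out hold fewer samples, yet the count rose without IPRN 1, so the number of samples was not the only factor. Of the 1047 genes called without IPRN 1, 757 were shared with the main fit. IPRN 1 also differed most from its replicates (chi-square per degree of freedom 89.9 and 97.6, against 48.8 between IPRN 2 and IPRN 3). On simulated counts DESeq2 made more false calls than edgeR (26.2% against 4.84%) but recovered more changed genes (47.8% against 25.4% at 1.5-fold). Those counts were drawn from dispersions estimated by edgeR, with few changed genes, so they cannot decide whether 938 or 2312 is nearer the truth. The cause of the differences between settings was not tested.

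With replicate number as a replicate block, 103 genes were called (18 rose and 85 fell), 49 of them at least 2-fold. The numbers gave no sign of pairing the samples. Deviations of same-numbered libraries from their group means had correlations of -0.175, 0.0864 and -0.13 across genes. These deviations cancel out within each group, so the correlations depend on one another. Those of DMSO 1 correlated best with those of IPRN 3 (0.237), and only IPRN 2 matched the library of its own number best. The block also moved the BMP list to an adjusted p of 0.0729 and ended no other list call.

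Lists were tested in every setting except DESeq2. In these settings the immediate early, inflammatory, cholesterol and myofibroblast lists kept their direction and call, except the myofibroblast list with an estimated correlation (0.176). That correlation also gave 0.108 for the ATF4, DNA replication, matrix turnover, p53 and unfolded protein lists, 0.217 for YAP and SRF targets and 0.234 for BMP targets. BMP targets lost their call at 50 counts (0.0851), with the liver term (0.0607), without both libraries (0.103), with robust dispersion (0.0513), and in 4 of 6 fits with 1 library left out (range 0.0213 to 0.149). The range over these fits was 0.0152 to 0.112 for ATF4, 0.0132 to 0.112 for matrix turnover, 0.0106 to 0.0522 for p53 and 0.0144 to 0.0998 for YAP and SRF, each highest without IPRN 1. DNA replication reached 0.0679 without both libraries, matrix turnover 0.163 at 50 counts and unfolded protein genes 0.183 under the restriction, which tested fewer genes. Under that restriction collagen and matrix genes, not called otherwise, were called down (0.0413), but the restriction dropped all 5 members that had risen. With fry, which does not compare a list with other genes, 14 lists were called, among them aryl hydrocarbon receptor (0.0193), NRF2 (0.0178) and WNT targets (0.0283), all down. Of 73 changed genes named by the fixed rule, 37 stayed called whichever library was left out and 36 did not. Without both libraries 51 lost their call, with the block 34, with the liver term 16, with no filter 5, and under the other scalings 0 did. At this depth, genes under the floor of 0.0382 to 0.0497 CPM could not be compared. Genes above that floor that failed the expression filter (a minimum count of 10) were not tested in the main fit either.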

Other observations

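The pathway tests and the tests of marker lists, gene copies and zinc finger genes were chosen after the results were seen. The count over other splits and the test of a single library were planned. Among 300 pathways as annotated in the deposited tables, camera called 12 at the preset correlation and 0 with an estimated correlation. IL-17 signalling had the smallest adjusted p, with 17 of 70 tested genes lower and 0 higher (median -0.11, adjusted p = 6.39e-11; adjusted p = 0.202 with an estimated correlation). Steroid biosynthesis had 5 of 16 genes lower (1.98e-05; adjusted p = 0.346 with an estimated correlation) and TNF signalling 15 of 100 lower and 3 higher (0.000244; adjusted p = 0.346 with an estimated correlation). A group outside the fixed lists was ribosome biogenesis, with 11 of 73 genes lower and 2 higher (median -0.13, 0.00100; adjusted p = 0.346 with an estimated correlation). Basal cell carcinoma, a set of Hedgehog and WNT signalling genes, had 5 of 41 genes higher and 0 lower (median 0.21, 0.00100; adjusted p = 0.666 with an estimated correlation). The Hedgehog and WNT signalling pathways themselves were not called by camera. Hedgehog had 4 of 40 genes higher and 1 lower (median 0.00335, camera adjusted p = 0.522). WNT had 4 of 117 genes higher and 4 lower (median 0.0357, camera adjusted p = 0.877).

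The split of the 6 libraries by treatment called 938 genes, and the highest of the other 9 splits called 5, so 1 of the 10 splits gave as many genes. With 10 splits the share cannot go under 0.1, too few to reach 0.05.

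In the immediate early and inflammatory lists, 21 of 30 and 13 of 27 tested genes fell under IPRN. A single library does not account for this, since the highest camera adjusted p of either list with any 1 library left out was 5.91e-17. A general loss of short-lived transcripts would have lowered zinc finger genes too. Yet the median log2 fold change of 329 of them was 0.111 (95% bootstrap interval over genes, not libraries, 0.0664 to 0.142), with 16 higher and 7 lower. This covers a single class of transcripts, so a loss limited to other short-lived transcripts was not tested. Reduced signalling upstream of the immediate early and inflammatory genes under IPRN and a difference in handling or harvest time between the groups were not tested either. All of these explanations stay open.

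Transcripts of liver were present in 4 libraries and nearly absent from DMSO 1 and IPRN 3. The 22 liver genes summed to 69.5 and 36.7 CPM in DMSO 2 and 3 and to 127 and 45.5 CPM in IPRN 1 and 2, against 0.348 CPM in DMSO 1 and 1.09 CPM in IPRN 3, and Alb, the albumin gene, led with up to 42.1 CPM. Expression by the NIH3T3 cells would be similar within a group, but the lowest library of a group held at most 2.39% of the next, and an effect of IPRN was argued against by 2 IPRN libraries lying below a DMSO library. RNA or reads from other mouse tissues stay open as the source, because log counts of the 22 genes, which are not independent, had Pearson r from 0.8004 to 0.895 over 6 pairs of the 4 libraries, but as low as 0.634 without Alb, under the bound of 0.8 set for it, and the share of Fgb in the liver counts differed 3.61-fold. Of the 22 genes, 2 had a count in DMSO 1, and 0 reached 1 CPM in every library.

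In the other marker lists, the 14 macrophage genes summed to 188 CPM in IPRN 3, led by Lyz2 at 99.3 CPM, against 3.53 to 20.1 CPM elsewhere. The 10 neural genes summed to 6.88 CPM in DMSO 1 and 2.06 CPM in IPRN 3, against 15.0 to 20.8 CPM in the others, and the 5 erythroid genes to 0.216 and 0 CPM, against 1.56 to 2.15 CPM. Lymphoid genes summed to 0 CPM in DMSO 1 and IPRN 3 and to between 0.270 and 0.743 CPM in the others. Kidney genes reached 0.941 CPM and lung genes 0.0552 CPM at most. Heart and muscle genes summed to 22.8 to 31.4 CPM in all 6 libraries, mostly from Tnnt2 at 20.2 to 28.2 CPM. Of these lists, 2 heart and muscle genes and 1 macrophage gene reached 1 CPM in every library. Lists fixed beforehand also held 5 of the macrophage, 3 of the heart and muscle, 2 of the neural and 2 of the lymphoid genes.

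Some genes with a mean of at least 5 CPM differed by at least 8-fold between libraries of one group. Rps18-ps4, a ribosomal protein pseudogene, had 784 CPM in IPRN 3 and 0 in the other 5 libraries, while its relative Rps18-ps6 had 0 in IPRN 3 and 766 to 814 CPM elsewhere. A difference from other tissues would set most such genes apart in DMSO 1 and IPRN 3, but 3 of 43 (6.98%) lay on one side in both, against 13.3% by chance. Reads shared between gene copies or overlapping models may account for them, since 38 of 42 with an annotation (90.5%) were pseudogenes or overlapped another gene on an exon, against 4355 of 10489 other genes at 5 CPM or more (41.5%; odds ratio 13.4, 95% interval 4.81 to 51.7, Fisher's exact p = 4.78e-11). No biological explanation was tested.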
